A study of Mus musculus with 79 samples.

How the data were processed

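RNA was taken from Th17 cells that had been labelled with a division dye and cultured under pathogenic or non-pathogenic conditions with EGCG, DHEA or the solvent of each. Unsorted cells and cells sorted after 1 division gave separate libraries. The labels describe 5 mice per condition. Libraries were made from polyadenylated RNA, trimmed with Trimmomatic and quantified with kallisto on mm10, with no versions or settings stated. The authors deposited 1 table in TPM, transcript abundances scaled for length and library size, with 1 value per gene symbol and library. How transcripts were summed to symbols was not stated, and the columns summed to between 880077 and 895017 TPM. No mitochondrially encoded genes were in the table. TPM keep no read counts, so depth per library was unknown and no counting interval could be given. Reads shared between members of gene families and pseudogenes could not be resolved from such a table.

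Groups were set from the library titles, and the comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The replicate numbers were the well columns of the titles. Replicates were treated as unpaired. The library of well A4 was left out because its label broke the layout of its row, and was put back in its labelled group as an alternative. All 152 pairs of libraries within a group were checked for duplicates, and their correlation across genes ran from 0.978 to 0.997.

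Of 20465 genes, 10674 with a TPM of at least 1 in at least 4 libraries were kept. Values were taken as log2(TPM + 1). Because of the pseudocount, the log2 changes of genes at low TPM understate the change in TPM. A linear model with 16 group means was fitted in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a trend on mean expression. Each comparison was a moderated two-sided test adjusted over the genes by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. There were 20 such comparisons. They comprised each compound against its solvent in each cell type and sort, the cell types against each other and the sorts against each other over both solvents, and the differences between cell types or sorts in the response to each compound. Adjustment was within a comparison and not across them. The change between cell types was also measured on up to 200 genes per direction, chosen by limma in the libraries of the other solvent, and tested with fry, which asks whether the signed genes move one way on balance and does not compare them with other genes. The 8 results of this kind were adjusted together.

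Gene lists written beforehand were tested with camera at a preset correlation of 0.01 if at least 5 members were kept, which held for 30 lists. They were adjusted over the lists within each of 12 comparisons, or 360 tests, of which 189 passed. With a correlation estimated from the data 46 passed, and that adjusted p stands beside each list. The count of members that passed over all genes stands beside that adjusted over the list alone. Markers of other cell types were summed in TPM per library.

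Named genes were the 6 with the largest increases and the 6 with the largest decreases among those called, with a mean of at least 5 TPM in the higher group and, for a compound against its solvent, no overlap between the libraries. For differences between responses they were 4 each way. To these were added up to 4 members of each list described with the smallest p, and a fixed set of cytokine, receptor, factor and metabolic genes. Predicted genes were passed over. The signature, glycolysis and pentose phosphate lists were always to be described, as was any list that camera called. The genes and lists given are a part of these, chosen after their values were seen. Gene positions were taken from an mm10 annotation, in which 19735 symbols were found.

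The alternatives were a pseudocount of 0.1, no filter on low values, TPM rescaled per library by the median ratio to the geometric mean of the kept genes, a fit on the groups compared alone, the well column as a block, the library of well A4 in its labelled group, an estimated correlation for the lists, and leaving out each library in turn. An alternative without the wells of columns 1 and 10 was added after seeing the data. The number of genes called was also computed for 100 splits of the libraries, the real one included. The procedure was tested on simulated data with 100 genes shifted by 0.5 and 100 by 1 on the log2 scale. With the group sizes of Th17n Div.1 cells it found 89% and 98% of them, with 5.56% of the calls false. Between the cell types in Total it found 96% and 98%, with 6.28% false, and for a difference between responses 72% and 95%, with 3.47% false. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the figures.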

Results

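Mouse T cells were labelled with a division dye, CFSE, and differentiated in culture into T helper 17 (Th17) cells of a pathogenic type (Th17p, with IL-1b, IL-6 and IL-23) or a non-pathogenic type (Th17n, with TGFb and IL-6). Each type was cultured with EGCG (epigallocatechin gallate, a green tea catechin) at 20 µM or with its solvent DMSO, and with DHEA at 50 µM or with its solvent methanol. From every culture condition RNA was taken from the unsorted cells (Total) and from cells sorted for exactly 1 division (Div.1). The deposited table held 79 libraries in 16 groups of cell type, treatment and sort. Every group was used with 5 libraries except the Th17p and the Th17n DMSO Div.1 groups, which had 4 each. The library of well A4 was labelled Th17n DMSO Div.1, while every other library of wells A1 to A5 was labelled Th17p DMSO Div.1, and it was left out. Between 9338 and 9845 genes per library reached 1 TPM, and the 10 most abundant genes took 6.90% to 8.35% of a library. The files held TPM alone, so the sequencing depth was unknown and counting error could not be separated from the spread between replicates.

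The main line of variation was the cell type. On the first principal component, with 45.5% of the variance, the Th17p and Th17n libraries stood apart. On the second component, with 10.9%, the libraries with EGCG or DHEA were displaced from those with solvent.

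**Figure D1:**
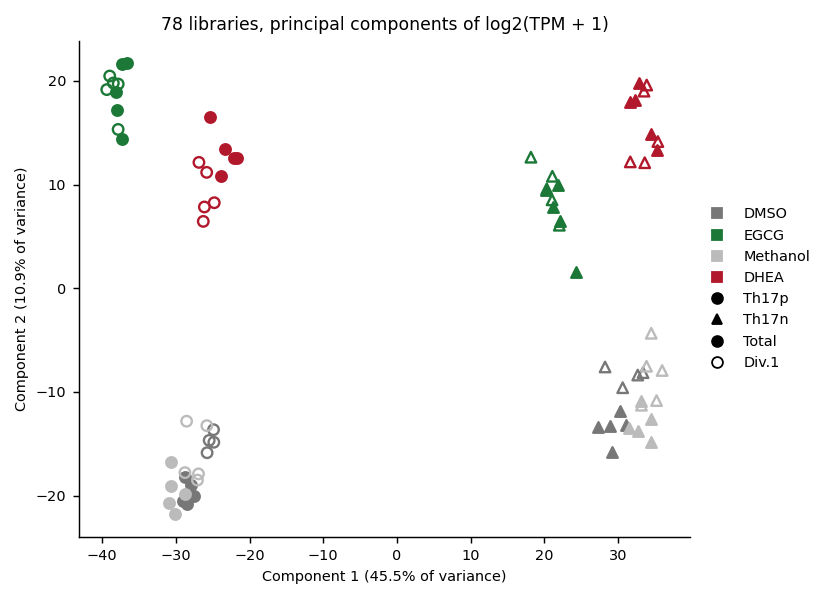
Principal components 1 (45.5% of the variance) and 2 (10.9%) of log2(TPM + 1) over the genes kept, with 1 point per library coloured by treatment. Component 1 separates the Th17p from the Th17n libraries.

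The solvent-treated Th17p and Th17n cells were compared to establish how the 2 differentiation conditions differed without either compound. Changes of genes and medians of lists are log2 changes on the scale of log2(TPM + 1). In the unsorted cells, Th17p cells carried the cytokine Il22 at 341 ± 60.5 TPM with DMSO and 259.7 ± 40.9 with methanol, against 6.77 ± 5.01 and 1.298 ± 1.37 in Th17n cells (SD, n = 5 per group; log2 change 6.37, SE 0.291, adjusted p = 3.24e-30). Il22 lies on chromosome 10 (mm10, 118204942 to 118210047, plus strand). The Th17n cells carried Foxp3, the transcription factor of regulatory T cells (chromosome X, 7573644 to 7595245, plus strand), at 59.9 ± 7.87 and 109.9 ± 15.1 TPM, where Th17p cells had 0.132 ± 0.143 and 0.121 ± 0.131 (log2 change -6.19, adjusted p = 1.3e-53). The Th17n cells also had more Il9 (-6.86), Il10 (-4.56), Maf (-4.58), Il17a (-2.22) and Il17f (-1.63), all log2 changes of Th17p over Th17n. Il17f reached 6801 ± 637 TPM in the Th17n and 2284 ± 368 in the Th17p cells with DMSO.

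Of the genes of a pathogenic Th17 signature, 13 of 15 were higher and 1 lower, as many when adjusted over the list alone. Their median was 2.24 (adjusted p = 1.69e-08, and adjusted p = 0.000315 with an estimated correlation). Il23r differed by 2.32, Casp1 by 2.70 and Tbx21, the Th1 factor T-bet, by 2.24. Of the genes of the non-pathogenic signature, 1 of 7 were higher and 6 lower, as many when adjusted over the list alone. The median was -3.23 (adjusted p = 2.02e-09, and adjusted p = 0.000145 with an estimated correlation). Ahr differed by -3.23 and Ikzf3 by -3.09. The TGFb targets were lower in Th17p cells: 0 of 12 were higher and 11 lower, as many when adjusted over the list alone. Their median was -0.93 (adjusted p = 4.78e-09, and adjusted p = 0.000145 with an estimated correlation). Ldlrad4 differed by -3.33, Skil by -2.05 and Pmepa1 by -2.22. Among Treg genes, 3 of 12 were higher and 9 lower, as many when adjusted over the list alone. The median was -1.39 (adjusted p = 0.00013, and adjusted p = 0.018 with an estimated correlation). Among Th1 genes, 7 of 9 were higher and 2 lower, as many when adjusted over the list alone. Their median was 1.96 (adjusted p = 0.000606, and adjusted p = 0.0234 with an estimated correlation). Il12rb2 differed by 3.61, Cxcr3 by 2.47 and Stat4 by 2.28. Of the core Th17 genes, 2 of 16 were higher and 12 lower, as many when adjusted over the list alone. The median was -1.09 (adjusted p = 5.48e-05, and adjusted p = 0.0313 with an estimated correlation). Glycolysis genes were higher in Th17p cells: 17 of 19 were higher and 0 lower, as many when adjusted over the list alone. Their median was 0.42 (adjusted p = 2.18e-07, and adjusted p = 0.146 with an estimated correlation). Hk2 differed by 0.86, Pfkl by 0.81 and Pgam1, a glycolytic mutase (chromosome 19, 41911923 to 41918660, plus strand), by 0.39. Among cholesterol synthesis genes, 19 of 23 were higher and 1 lower, as many when adjusted over the list alone. The median was 0.34 (adjusted p = 0.00013, and adjusted p = 0.273 with an estimated correlation). The pentose phosphate genes showed no shift as a list: 5 of 12 were higher and 3 lower, as many when adjusted over the list alone. Their median was 0.04 (adjusted p = 0.693, and adjusted p = 0.807 with an estimated correlation), although G6pdx, which encodes the first enzyme of the pathway, was higher by 0.37 (adjusted p = 3.21e-12). Among the furthest apart were Lum (6.88), Ifitm3 (4.51) and S100a6 (4.50) toward Th17p and the water channel gene Aqp3 (-8.72), Ctsw (-6.66), Pdpn (-6.62) and Ccl20 (-5.91) toward Th17n. In all, 6127 of 10674 genes differed, 3298 higher and 2829 lower in Th17p, or 3151 and 3021 after rescaling. CD8 T and NK cell markers summed to 6.53 ± 1.82 (DMSO) and 9.60 ± 1.36 TPM (methanol) in Th17p and 18.45 ± 4.35 and 23.5 ± 2.78 in Th17n, and B cell markers to 9.03 ± 1.77 and 9.17 ± 1.7 against 5.7 ± 1.99 and 4.96 ± 1.07. Csf2 and Ifng were too low to be tested. Ifng reached 3.098 and 1.044 TPM in 2 libraries of Th17p DHEA Div.1.

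In Div.1 cells 6465 genes differed between the types, 3727 higher and 2738 lower in Th17p, or 3232 and 3180 after rescaling. Il22 (6.23), Il23r (2.97) and Tbx21 (1.93) were again higher in Th17p, and Foxp3 (-6.64), Il9 (-7.74), Aqp3 (-8.37), Il17a (log2 change -1.54, adjusted p = 4.84e-05) and Il17f (log2 change -1.3, adjusted p = 6.32e-12) lower. Of the pathogenic genes, 12 of 15 were higher and 1 lower, as many when adjusted over the list alone. The median was 1.97 (adjusted p = 4.82e-07, and adjusted p = 0.00172 with an estimated correlation). Of the non-pathogenic genes, 0 of 7 were higher and 6 lower, or 1 and 6 adjusted over the list alone. Their median was -3.11 (adjusted p = 2.19e-09, and adjusted p = 0.000232 with an estimated correlation). Of glycolysis genes, 19 of 19 were higher and 0 lower, as many when adjusted over the list alone. The median was 0.55 (adjusted p = 2.28e-09, and adjusted p = 0.0717 with an estimated correlation). Tpi1 differed by 0.87, Aldoa by 0.76 and Pgam1 by 0.53. Among TGFb targets, 0 of 12 were higher and 11 lower, as many when adjusted over the list alone. Their median was -0.93 (adjusted p = 9.3e-09, and adjusted p = 0.000232 with an estimated correlation).

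**Figure D2:**
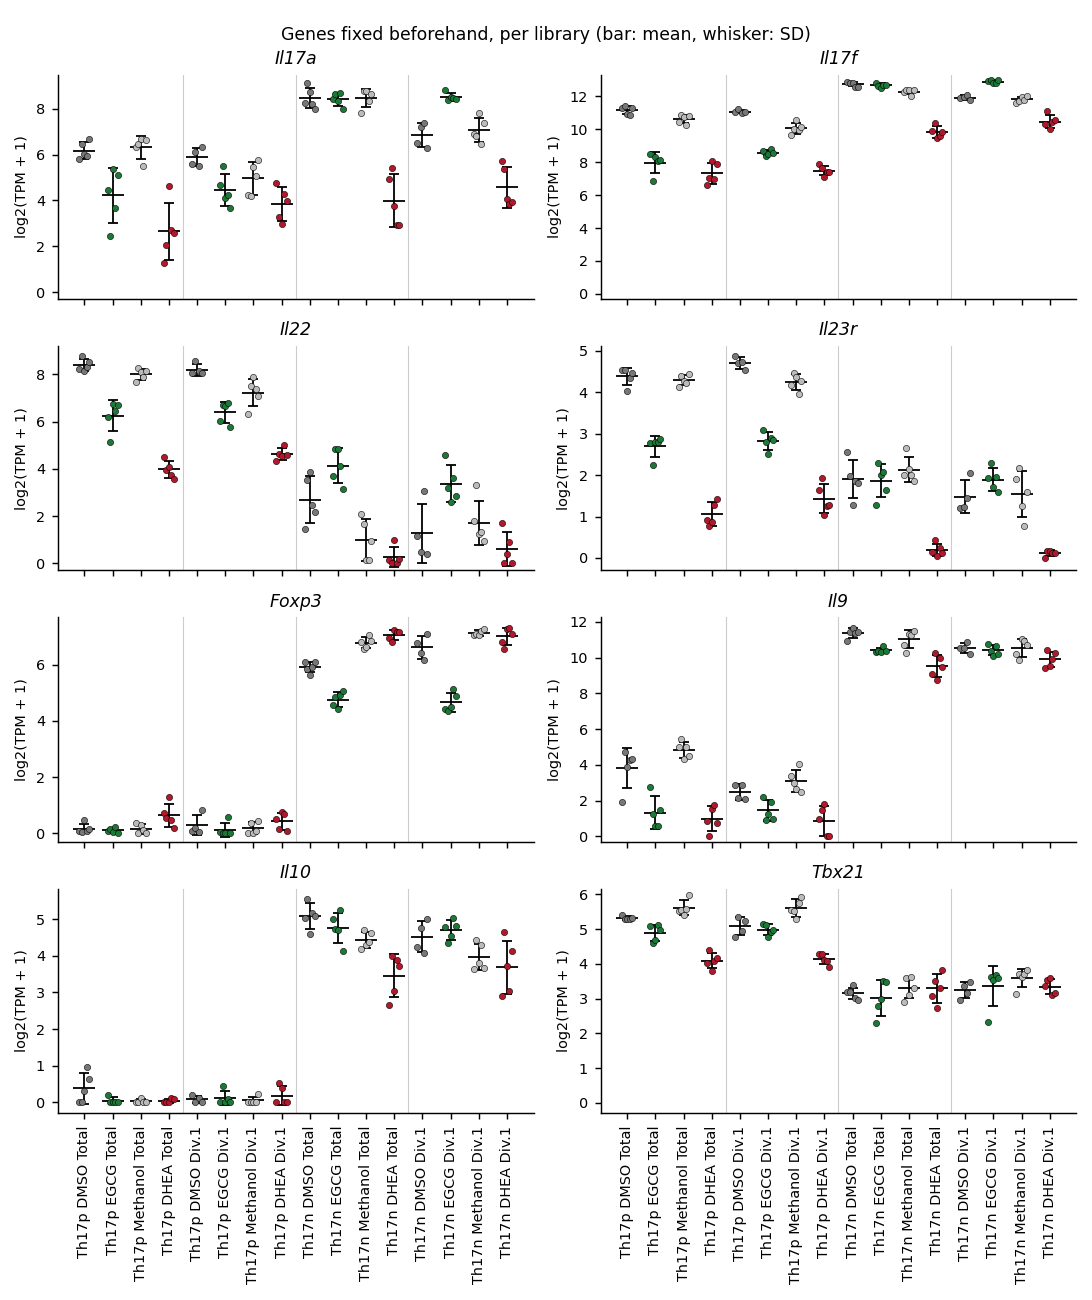
Level of 8 genes fixed beforehand as log2(TPM + 1) in each group, with 1 point per library, a bar at the group mean and a whisker of 1 SD. Il17f with DMSO in unsorted cells averages 2284 TPM in Th17p and 6801 TPM in Th17n cells.

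EGCG was compared with DMSO in unsorted Th17p cells to see what it changed in cells made under pathogenic conditions. The Th17 cytokine genes were lower: Il17f (chromosome 1, 20777146 to 20790617, minus strand) fell from 2284 ± 368 to 268 ± 93.6 TPM (SD, n = 5 and 5; log2 change -3.17, SE 0.196, adjusted p = 2.78e-22). Il22 fell from 341 ± 60.5 to 80.9 ± 29.8 TPM (log2 change -2.15, adjusted p = 1.31e-05), Il17a from 73.3 ± 19.7 to 22.2 ± 14.8 (log2 change -1.96, adjusted p = 0.000179), and Il23r, the IL-23 receptor gene, from 20.1 ± 2.93 to 5.56 ± 1.02 (log2 change -1.69, adjusted p = 1.23e-11). Genes activated by p53 rose together: Cdkn1a, which encodes the cell cycle inhibitor p21, went from 60.5 ± 14.7 to 464 ± 41.3 TPM (log2 change 2.95, SE 0.167, adjusted p = 3.45e-24). Il2, the growth factor gene of activated T cells, rose from 1287 ± 158 to 5292 ± 514 TPM (log2 change 2.04, adjusted p = 2.48e-13).

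Of p53 targets, 15 of 16 rose and 0 fell, or 16 and 0 adjusted over the list alone. The median was 1.36 (adjusted p = 1.17e-16, and adjusted p = 0.000971 with an estimated correlation). Phlda3 changed by 3.58, Zmat3 by 2.04 and Ccng1 by 1.67. Genes of the G2 and M phases fell: 0 of 26 rose and 22 fell, as many when adjusted over the list alone. Their median was -0.50 (adjusted p = 1.17e-16, and adjusted p = 0.0275 with an estimated correlation). Plk1 changed by -0.88, Ccnb1 by -0.81 and Cdc20 by -0.74. Among G1 and S phase genes, 1 of 25 rose and 18 fell, or 2 and 18 adjusted over the list alone. The median was -0.27 (adjusted p = 1.81e-09, and adjusted p = 0.0353 with an estimated correlation). T cell receptor activation genes were higher: 14 of 17 rose and 1 fell, as many when adjusted over the list alone. Their median was 1.01 (adjusted p = 4.36e-07, and adjusted p = 0.0275 with an estimated correlation). Cd69 changed by 1.53 and Tnfrsf4 by 1.13. Among genes of naive and quiescent T cells, 10 of 15 rose and 1 fell, or 11 and 1 adjusted over the list alone. The median was 0.76 (adjusted p = 1.85e-05, and adjusted p = 0.05 with an estimated correlation). Bach2 changed by 1.3, Btg2 by 1.44 and Ccr7 by 1.06. Of core Th17 genes, 0 of 16 rose and 7 fell, as many when adjusted over the list alone. Their median was -0.20 (adjusted p = 0.000181, and adjusted p = 0.0451 with an estimated correlation). Il1r1 changed by -1.52 and Batf by -0.37. The pathogenic signature moved both ways, as 9 of 15 rose and 3 fell, or 9 and 4 adjusted over the list alone. The median was 0.83 (adjusted p = 0.123, and adjusted p = 0.282 with an estimated correlation). Among those that rose, Lgals3 changed by 1.94 and Stat4 by 0.92. Of the non-pathogenic genes, 1 of 7 rose and 4 fell, as many when adjusted over the list alone. Their median was -0.34 (adjusted p = 0.00805, and adjusted p = 0.0927 with an estimated correlation). Il1rn, the antagonist of the IL-1 receptor, changed by -3.23 and Il9 by -2.48.

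Several biosynthetic lists were lower with EGCG in these cells. Among glycolysis genes, 1 of 19 rose and 14 fell, or 1 and 15 adjusted over the list alone. The median was -0.24 (adjusted p = 2.71e-07, and adjusted p = 0.0935 with an estimated correlation). Hk2 changed by -0.61, Aldoa by -0.51 and Pgam1 by -0.42. The pentose phosphate genes moved little as a list, as 1 of 12 rose and 4 fell, as many when adjusted over the list alone. Their median was -0.02 (adjusted p = 0.0173, and adjusted p = 0.168 with an estimated correlation). G6pdx (chromosome X, 74409483 to 74429194, minus strand) changed by -0.49 and Pgd by -0.50. In fatty acid synthesis, 1 of 12 rose and 11 fell, as many when adjusted over the list alone. The median was -0.46 (adjusted p = 7.7e-08, and adjusted p = 0.0372 with an estimated correlation). The desaturase genes Scd1 and Scd2 changed by -2.18 and -1.35. In cholesterol synthesis, 0 of 23 rose and 17 fell, or 0 and 18 adjusted over the list alone. Their median was -0.30 (adjusted p = 4.8e-09, and adjusted p = 0.0578 with an estimated correlation). Fdps changed by -0.94. In serine and one-carbon metabolism, 1 of 12 rose and 9 fell, as many when adjusted over the list alone. The median was -0.36 (adjusted p = 1.16e-07, and adjusted p = 0.0275 with an estimated correlation). Phgdh changed by -0.78 and Shmt2 by -0.72. Among ATF4 targets, which respond to amino acid stress, 4 of 25 rose and 16 fell, as many when adjusted over the list alone. Their median was -0.46 (adjusted p = 2.67e-08, and adjusted p = 0.0875 with an estimated correlation). Chac1 changed by -3.50 and Trib3 by -2.62. Of heat shock genes, 0 of 10 rose and 8 fell, as many when adjusted over the list alone. The median was -0.32 (adjusted p = 1.36e-07, and adjusted p = 0.0275 with an estimated correlation). Hspa8 changed by -0.46. Fatty acid oxidation genes went the other way, as 13 of 17 rose and 0 fell, or 14 and 1 adjusted over the list alone. Their median was 0.27 (adjusted p = 0.000535, and adjusted p = 0.0451 with an estimated correlation). Slc25a20 changed by 0.72 and Etfdh by 0.63. Among the largest increases were Serpine2 (4.63), the costimulatory ligand gene Tnfsf4 (4.19) and Phlda3, and among the largest decreases Chac1, Ildr1 (-3.35) and Il1rn. The CD8 T and NK cell markers summed to 10.99 ± 1.89 TPM with EGCG and 6.53 ± 1.82 with DMSO. In all 4794 genes changed, 3208 higher and 1586 lower, of which 285 and 75 changed at least 2-fold. With TPM rescaled by the median ratio the split was 2506 higher and 2256 lower, so the excess of increases over decreases depended on the scaling. Maf (log2 change -0.19, adjusted p = 0.194), Il10 and Foxp3 did not pass the test, and the call of Tbx21 (log2 change -0.44, adjusted p = 0.0444) was lost on leaving out any of 8 libraries in turn, furthest without Th17p EGCG Total replicate 2 (-0.37, adjusted p = 0.125).

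In Th17p Div.1 cells the cytokine genes were also lower with EGCG. Il17f fell from 2149 ± 162 (n = 4) to 384 ± 46.8 TPM (n = 5; log2 change -2.48, adjusted p = 2.87e-16), with Il23r at -1.88, Il22 at -1.82 and Il17a at -1.44 (adjusted p = 0.00884). Cdkn1a rose from 57.9 ± 7.58 to 503 ± 24.3 TPM (log2 change 3.11, adjusted p = 8.54e-24). Of p53 targets, 16 of 16 rose and 0 fell, as many when adjusted over the list alone. The median was 1.61 (adjusted p = 1.29e-17, and adjusted p = 0.00061 with an estimated correlation). Phlda3 changed by 4.12 and Ccng1 by 1.90. Among G2 and M phase genes, 0 of 26 rose and 21 fell, or 0 and 22 adjusted over the list alone. Their median was -0.49 (adjusted p = 9.51e-19, and adjusted p = 0.0313 with an estimated correlation). Plk1 changed by -0.92. The glycolysis genes were lower, as 0 of 19 rose and 12 fell, as many when adjusted over the list alone. The median was -0.18 (adjusted p = 1.41e-06, and adjusted p = 0.124 with an estimated correlation). Pgam1 changed by -0.30. Of the receptor activation genes, 14 of 17 rose and 1 fell, or 15 and 1 adjusted over the list alone. Their median was 1.02 (adjusted p = 4.45e-05, and adjusted p = 0.0664 with an estimated correlation). Il2 changed by 2.16 and Cd69 by 1.38. Of core Th17 genes, 0 of 16 rose and 6 fell, as many when adjusted over the list alone. The median was -0.24 (adjusted p = 0.000355, and adjusted p = 0.0664 with an estimated correlation). Of the non-pathogenic genes, 0 of 7 rose and 5 fell, as many when adjusted over the list alone. Their median was -0.65 (adjusted p = 0.000832, and adjusted p = 0.0664 with an estimated correlation). Maf changed by -0.54, at a low level of 1.044 TPM with DMSO and 0.414 with EGCG. Penk (4.24), Serpine2 (4.11), Tnfsf4 (3.68) and the costimulatory ligand gene Cd70 (3.35) rose among the furthest, and Ildr1 (-2.92), Plac8 (-2.36) and Tnfrsf8 (-2.22) fell among the furthest. The CD8 T and NK cell markers summed to 12.5 ± 1.44 TPM with EGCG and 9.61 ± 0.919 with DMSO. Of 4869 genes changed, 3601 were higher and 1268 lower, against 2430 and 2240 after rescaling, which moved the median of all genes by -0.103. The call of Il9 (log2 change -1.03, adjusted p = 0.0251) was lost on leaving out any of 4 libraries in turn, furthest without Th17p DMSO Div.1 replicate 1 (-0.90, adjusted p = 0.0827).

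In unsorted Th17n cells EGCG was compared with DMSO to see what it changed under non-pathogenic conditions. Foxp3 fell from 59.9 ± 7.87 to 26.4 ± 4.79 TPM (SD, n = 5 and 5; log2 change -1.16, SE 0.161, adjusted p = 3.35e-08). Il17a (log2 change -0.05, adjusted p = 0.942), Il17f (-0.07, adjusted p = 0.825) and Il23r (-0.04, adjusted p = 0.896) did not pass the test, with Il17f at 6801 ± 637 TPM with DMSO and 6485 ± 523 with EGCG. Il22 rose from 6.77 ± 5.01 to 18.3 ± 9.03 TPM (log2 change 1.44, adjusted p = 0.00435), and Il2 from 163 ± 46.2 to 724 ± 134 (log2 change 2.17, adjusted p = 1.32e-13). As in Th17p cells, the p53 targets rose: 13 of 16 rose and 0 fell, or 14 and 0 adjusted over the list alone. The median was 0.73 (adjusted p = 8.61e-15, and adjusted p = 0.00211 with an estimated correlation). Cdkn1a changed by 3.45, Ccng1 by 1.5 and Bax by 0.88. Of G2 and M phase genes, 0 of 26 rose and 15 fell, or 1 and 17 adjusted over the list alone. Their median was -0.21 (adjusted p = 2.28e-07, and adjusted p = 0.177 with an estimated correlation). Ccnb1 changed by -0.51. The receptor activation genes were higher, as 11 of 17 rose and 1 fell, or 12 and 1 adjusted over the list alone. The median was 0.68 (adjusted p = 5.9e-05, and adjusted p = 0.0994 with an estimated correlation). So were the interferon response genes, as 7 of 12 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.26 (adjusted p = 0.00807, and adjusted p = 0.0994 with an estimated correlation). Gbp2 changed by 1.20. Of Th1 genes, 4 of 9 rose and 0 fell, as many when adjusted over the list alone. The median was 0.41 (adjusted p = 0.0175, and adjusted p = 0.136 with an estimated correlation). Il12rb2 changed by 1.23 and Cxcr3 by 0.76. Among inhibitory receptor genes, 5 of 8 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.48 (adjusted p = 0.0398, and adjusted p = 0.161 with an estimated correlation). Ctla4 changed by 0.99 and Pdcd1 by 0.64. Genes of naive and quiescent cells were higher, as 9 of 15 rose and 0 fell, or 10 and 0 adjusted over the list alone. The median was 0.35 (adjusted p = 0.000175, and adjusted p = 0.136 with an estimated correlation). Il7r changed by 1.09. The glycolysis genes did not pass as a list, as 7 of 19 rose and 2 fell, as many when adjusted over the list alone. Their median was 0.09 (adjusted p = 0.649, and adjusted p = 0.862 with an estimated correlation), and neither Pgam1 (-0.08, adjusted p = 0.168) nor G6pdx (-0.09, adjusted p = 0.222) passed. Of the pathogenic genes, 7 of 15 rose and 0 fell, as many when adjusted over the list alone. The median was 0.24 (adjusted p = 0.159, and adjusted p = 0.415 with an estimated correlation). Of the non-pathogenic genes, 1 of 7 rose and 4 fell, as many when adjusted over the list alone. Their median was -0.40 (adjusted p = 0.059, and adjusted p = 0.284 with an estimated correlation). Ahr changed by -0.40 and Ikzf3 by -0.40. The adenylate kinase gene Ak1 (4.14), Cdkn1a, Serpine2 (2.99) and S100a6 (2.70) rose among the furthest, and Chac1 (-2.54), Pcgf6 (-1.39) and Zfand5 (-1.33) fell among the furthest. Of 3760 genes changed, 2319 were higher and 1441 lower, against 1908 and 1912 after rescaling. B cell markers summed to 8.84 ± 1.7 TPM with EGCG and 5.7 ± 1.99 with DMSO. The call of Il9 (log2 change -0.96, adjusted p = 0.0357) was lost on leaving out any of 8 libraries in turn, furthest without Th17n DMSO Total replicate 3 (-0.88, adjusted p = 0.078).

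In Th17n Div.1 cells the Th17 cytokine genes were higher with EGCG. Il17f rose from 3867 ± 354 (n = 4) to 7597 ± 554 TPM (n = 5; log2 change 0.97, SE 0.208, adjusted p = 0.000131), Il17a from 120.1 ± 43.2 to 368 ± 44.3 (log2 change 1.67, adjusted p = 0.00362), and Il22 from 2.32 ± 3.39 to 10.8 ± 7.39 (log2 change 2.10, adjusted p = 8.94e-05). The chemokine gene Ccl20 rose from 59.5 ± 29 to 365 ± 62.2 TPM (log2 change 2.70, adjusted p = 7.66e-09), while Foxp3 fell from 100.2 ± 28.1 to 25.04 ± 6.51 (log2 change -1.95, adjusted p = 5.89e-15). Of p53 targets, 14 of 16 rose and 0 fell, or 15 and 0 adjusted over the list alone. The median was 0.87 (adjusted p = 6.49e-16, and adjusted p = 0.00121 with an estimated correlation). Cdkn1a changed by 3.43 and Ccng1 by 1.99. Of G2 and M phase genes, 0 of 26 rose and 11 fell, or 0 and 12 adjusted over the list alone. Their median was -0.18 (adjusted p = 7.44e-09, and adjusted p = 0.256 with an estimated correlation). Cdc20 changed by -0.49. Hypoxia genes were higher, as 10 of 17 rose and 0 fell, or 11 and 0 adjusted over the list alone. The median was 0.39 (adjusted p = 0.0134, and adjusted p = 0.366 with an estimated correlation). Of Th1 genes, 6 of 9 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.63 (adjusted p = 0.0148, and adjusted p = 0.233 with an estimated correlation). Il18rap changed by 0.95 and Il12rb2 by 0.89. Of fatty acid oxidation genes, 12 of 17 rose and 0 fell, or 13 and 0 adjusted over the list alone. The median was 0.27 (adjusted p = 0.00559, and adjusted p = 0.233 with an estimated correlation). Plin2 changed by 1.19. Of core Th17 genes, 8 of 16 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.43 (adjusted p = 0.0512, and adjusted p = 0.449 with an estimated correlation). Of glycolysis genes, 7 of 19 rose and 0 fell, as many when adjusted over the list alone. The median was 0.17 (adjusted p = 0.283, and adjusted p = 0.739 with an estimated correlation). Hk2 changed by 0.44 and Pgam1 by 0.15, while G6pdx did not pass (adjusted p = 0.984). Ak1 (4.21), Tnfsf4 (3.42) and Il2 (2.87) rose among the furthest, and Sgk1 (-1.45), Serpinb1a (-1.3) and Emp1 (-1.29) fell among the furthest. Of 3720 genes changed, 2997 were higher and 723 lower, against 1642 and 1671 after rescaling, which moved the median of all genes by -0.112 and Pgam1 to 0.024 (adjusted p = 0.645). B cell markers summed to 10.2 ± 0.884 TPM with EGCG and 4.75 ± 1.52 with DMSO, and CD8 T and NK cell markers to 17.9 ± 2.53 and 23.4 ± 4.36.

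**Figure D3:**
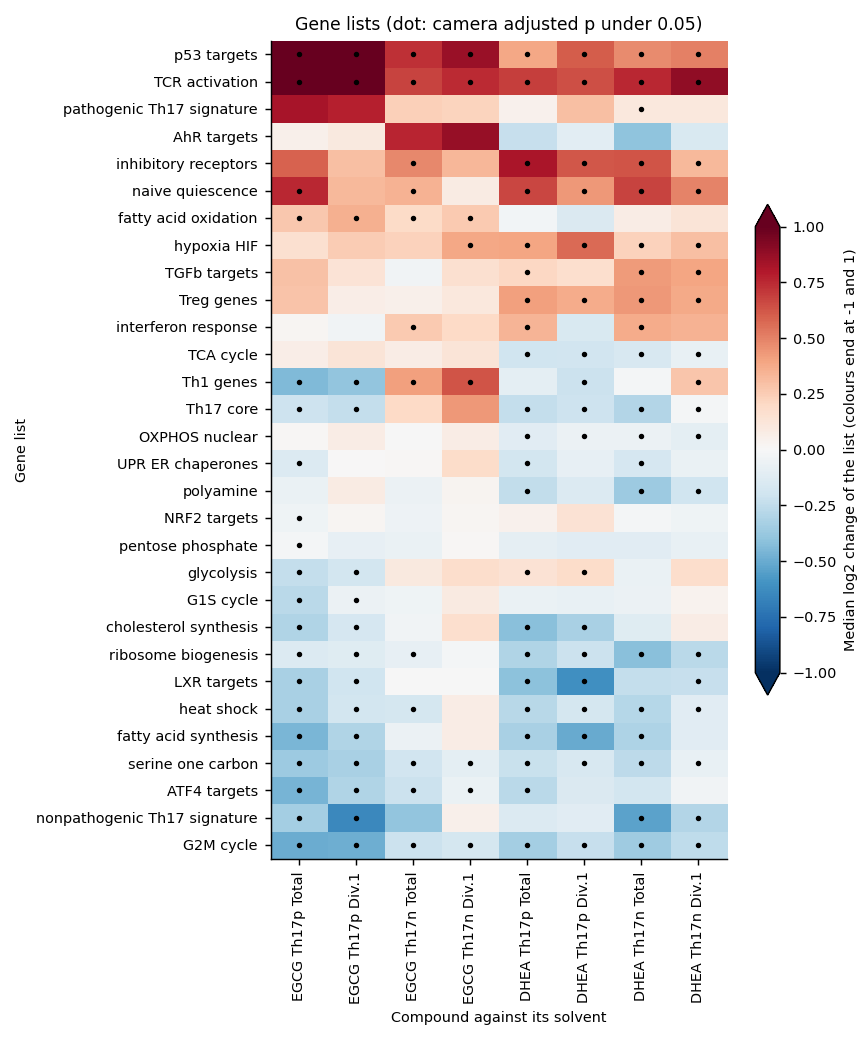
Median log2 change of each gene list for EGCG or DHEA against its solvent, by cell type and sort, on a colour scale that ends at -1 and 1, with a dot where camera gave an adjusted p under 0.05. The p53 targets are positive in all 8 comparisons, from 0.39 to 1.61.

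The responses of the 2 cell types to EGCG were then compared directly, as the effect in Th17p minus that in Th17n. In unsorted cells 2127 genes differed, 1321 of them higher, or 1206 of 2330 after rescaling. The difference was negative for Il22 (log2 change -3.59, adjusted p = 3.51e-06), Il17f (log2 change -3.10, adjusted p = 1.47e-13), Il23r (log2 change -1.65, adjusted p = 3.1e-06), Pgam1 (log2 change -0.34, adjusted p = 2.81e-05) and G6pdx (log2 change -0.40, adjusted p = 0.000187), and positive for the RANK ligand gene Tnfsf11 (2.83) and Il3 (2.63). For Il17a it was -1.91 (adjusted p = 0.0215), and the call was lost without Th17p EGCG Total replicate 2 (-1.47, adjusted p = 0.0853). In Div.1 cells 1867 genes differed, 973 of them higher, or 1048 of 2034 after rescaling. Il22 (-3.92), Il17f (-3.46), Il17a (log2 change -3.11, adjusted p = 0.000314), Il23r (-2.29), Pgam1 (log2 change -0.45, adjusted p = 6e-07) and Maf (-0.69) were negative, and Dusp2 (3.02) and Ccl1 (3.07) positive. Il17a, Il17f and Il22 thus moved in opposite directions in the Div.1 cells of the 2 types, each past the test in both. So did Pgam1 before rescaling.

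The response to EGCG was then compared between the sorts, as its effect in Div.1 minus that in Total. Sorting and division number cannot be told apart in this difference. In Th17p cells 274 genes differed, 144 of them higher, or 127 of 373 after rescaling. The count was 160 with the library of well A4, 467 without columns 1 and 10 and 479 in a fit on the groups compared alone. The metallothionein gene Mt1 (log2 change 1.31, adjusted p = 0.000102) and Pdzk1ip1 (log2 change 1.63, adjusted p = 0.00032) were more positive in Div.1 and 4 histone genes more negative, with Hist1h2ai (log2 change -3.12, adjusted p = 2.13e-08) first, and no tested gene of the fixed list differed. In Th17n cells 1420 genes differed, 1150 of them higher, or 784 of 1499 after rescaling. Il17f (log2 change 1.04, adjusted p = 0.00812), Ccl20 (log2 change 1.88, adjusted p = 0.00576) and Pgam1 (log2 change 0.23, adjusted p = 0.00925) were higher in the Div.1 response, and Ly6c1 (log2 change -1.22, adjusted p = 0.00309) lower. Il17a was at 1.72 and did not pass (adjusted p = 0.0633), and the call of Foxp3 (log2 change -0.79, adjusted p = 0.0152) was lost without Th17n DMSO Div.1 replicate 4 (-0.64, adjusted p = 0.0675) and turned to 0.434 with the library of well A4 (adjusted p = 0.732).

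DHEA was compared with methanol in unsorted Th17p cells to see what it changed under pathogenic conditions. The Th17 cytokine genes were lower: Il22 fell from 259.7 ± 40.9 to 15.2 ± 4.19 TPM (SD, n = 5 and 5; log2 change -4.03, SE 0.412, adjusted p = 5.5e-13), Il17f from 1573 ± 255 to 171 ± 74.9 (log2 change -3.28, adjusted p = 9.29e-23), and Il17a from 82.0 ± 23.3 to 7.83 ± 9.16 (log2 change -3.66, adjusted p = 1.44e-10). Il23r (chromosome 6, 67422932 to 67491855, minus strand) fell from 18.7 ± 1.73 to 1.11 ± 0.433 TPM (log2 change -3.24, adjusted p = 2.06e-23) and Tbx21 (chromosome 11, 97098071 to 97115331, minus strand) from 48.2 ± 7.92 to 16.2 ± 2.7 (log2 change -1.52, adjusted p = 1.36e-10). Ccr7, a chemokine receptor gene of naive cells, rose from 247 ± 30.3 to 780.3 ± 77.1 TPM. Gzmb, which encodes the cytotoxic protease granzyme B, rose from 7.58 ± 2.13 to 87.1 ± 22.9 TPM (log2 change 3.35, adjusted p = 1.64e-20).

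Of genes of naive and quiescent T cells, 13 of 15 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.67 (adjusted p = 1.42e-09, and adjusted p = 0.0191 with an estimated correlation). Ccr7 changed by 1.66 and Tcf7 by 1.28. Of hypoxia genes, 12 of 17 rose and 0 fell, or 13 and 0 adjusted over the list alone. The median was 0.39 (adjusted p = 1.83e-05, and adjusted p = 0.0704 with an estimated correlation). Bnip3 changed by 1.55 and Ndrg1 by 1.38. Receptor activation genes were higher, as 12 of 17 rose and 1 fell, as many when adjusted over the list alone. Their median was 0.69 (adjusted p = 3.23e-06, and adjusted p = 0.0704 with an estimated correlation). Tnfrsf9 changed by 2.70 and Nr4a3 by 2.15. Of Treg genes, 6 of 12 rose and 1 fell, as many when adjusted over the list alone. The median was 0.41 (adjusted p = 0.00189, and adjusted p = 0.0704 with an estimated correlation). Gpr83 changed by 1.39. Of inhibitory receptor genes, 5 of 8 rose and 1 fell, as many when adjusted over the list alone. Their median was 0.81 (adjusted p = 0.00497, and adjusted p = 0.0704 with an estimated correlation). Lag3 changed by 1.23 and Ctla4 by 1.23. Cholesterol synthesis genes were lower, as 0 of 23 rose and 17 fell, or 0 and 18 adjusted over the list alone. The median was -0.42 (adjusted p = 3.59e-07, and adjusted p = 0.116 with an estimated correlation). Lss changed by -1.11. So were those of fatty acid synthesis, as 0 of 12 rose and 10 fell, or 0 and 11 adjusted over the list alone. Their median was -0.32 (adjusted p = 3.75e-06, and adjusted p = 0.1 with an estimated correlation). Scd1 changed by -3.51 and Fads2 by -2.12. Of ribosome biogenesis genes, 0 of 20 rose and 18 fell, or 1 and 18 adjusted over the list alone. The median was -0.30 (adjusted p = 3.98e-07, and adjusted p = 0.116 with an estimated correlation). Wdr43 changed by -0.51. Of G2 and M phase genes, 0 of 26 rose and 21 fell, or 1 and 21 adjusted over the list alone. Their median was -0.34 (adjusted p = 5.99e-06, and adjusted p = 0.192 with an estimated correlation). Of the citric acid cycle genes, 2 of 21 rose and 14 fell, or 2 and 16 adjusted over the list alone. The median was -0.20 (adjusted p = 0.000194, and adjusted p = 0.194 with an estimated correlation). Idh1 changed by -2.14. Glycolysis genes moved both ways, as 10 of 19 rose and 4 fell, as many when adjusted over the list alone. Their median was 0.14 (adjusted p = 0.02, and adjusted p = 0.428 with an estimated correlation). Slc16a3 changed by 2.02, Gpi1 by 0.43, Tpi1 by 0.42 and Pgam1 by -0.15. Of pentose phosphate genes, 3 of 12 rose and 4 fell, or 3 and 5 adjusted over the list alone. The median was -0.09 (adjusted p = 0.475, and adjusted p = 0.662 with an estimated correlation). G6pdx changed by -0.35. Of core Th17 genes, 2 of 16 rose and 7 fell, or 3 and 7 adjusted over the list alone. Their median was -0.23 (adjusted p = 0.00939, and adjusted p = 0.17 with an estimated correlation). Il1r1 changed by -2.08 and Batf by -1.0. The pathogenic signature had no common direction and a test direction opposite to its median, as 6 of 15 rose and 5 fell, as many when adjusted over the list alone. The median was 0.05 (adjusted p = 0.746, and adjusted p = 0.818 with an estimated correlation). The non-pathogenic signature had none either, as 2 of 7 rose and 3 fell, as many when adjusted over the list alone. Their median was -0.14 (adjusted p = 0.729, and adjusted p = 0.816 with an estimated correlation). Il9 changed by -3.85. The largest decreases included Ccl3 (-4.09) and Timp1 (-3.72), and the largest increases Akr1c18, a steroid dehydrogenase gene (3.14), Ms4a4b (2.91) and Ecm1 (2.85). The summed TPM of 10 B cell markers was 24.8 ± 3.61 with DHEA and 9.17 ± 1.7 with methanol, and that of 8 CD8 T and NK cell markers 19.4 ± 3 and 9.60 ± 1.36. Of 5095 genes changed, 2236 were higher and 2859 lower (2593 and 2534 after rescaling), and 247 and 100 changed at least 2-fold. The call of Foxp3 (log2 change 0.48, adjusted p = 0.00999) was lost without Th17p DHEA Total replicate 8 (0.32, adjusted p = 0.0976), and that of Maf (log2 change -0.28, adjusted p = 0.0423) was lost on leaving out any of 4 libraries, furthest without Th17p Methanol Total replicate 10 (-0.19, adjusted p = 0.208).

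In Th17p Div.1 cells DHEA lowered Il22 from 159 ± 57.5 to 23.9 ± 4.66 TPM (log2 change -2.61, adjusted p = 4.26e-07) and Il17f from 1088 ± 263 to 181 ± 37.2 (log2 change -2.57, adjusted p = 2.35e-17), with Il23r at -2.81 and Tbx21 at -1.47. Of hypoxia genes, 14 of 17 rose and 0 fell, as many when adjusted over the list alone. The median was 0.56 (adjusted p = 4.12e-09, and adjusted p = 0.0106 with an estimated correlation). Bnip3 changed by 1.89. Of genes of naive and quiescent cells, 12 of 15 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.43 (adjusted p = 3.55e-08, and adjusted p = 0.0236 with an estimated correlation). Of receptor activation genes, 14 of 17 rose and 1 fell, as many when adjusted over the list alone. The median was 0.64 (adjusted p = 8.99e-08, and adjusted p = 0.0236 with an estimated correlation). Of p53 targets, 11 of 16 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.60 (adjusted p = 9.12e-08, and adjusted p = 0.0241 with an estimated correlation). Phlda3 changed by 2.29 and Cdkn1a by 1.55. Of fatty acid synthesis genes, 0 of 12 rose and 10 fell, as many when adjusted over the list alone. The median was -0.51 (adjusted p = 3.46e-08, and adjusted p = 0.0241 with an estimated correlation). Scd1 changed by -3.04. Of glycolysis genes, 12 of 19 rose and 1 fell, or 13 and 1 adjusted over the list alone. Their median was 0.18 (adjusted p = 1.2e-05, and adjusted p = 0.153 with an estimated correlation). Tpi1 changed by 0.53 and Pgk1 by 0.40, while Pgam1 did not pass (adjusted p = 0.151). Gzmb (3.35) and the class II gene H2-Ab1 (2.44) rose among the furthest, and Ildr1 (-3.07) fell among the furthest. B cell markers summed to 27.4 ± 2.9 TPM against 8.83 ± 2.21 with methanol, and CD8 T and NK cell markers to 19.5 ± 4.69 against 11.1 ± 1.04. Of 3982 genes changed, 1934 were higher and 2048 lower, or 2026 and 2114 after rescaling. The call of Il17a (log2 change -1.11, adjusted p = 0.0398) was lost on leaving out any of 6 libraries in turn, furthest without Th17p DHEA Div.1 replicate 8 (-0.89, adjusted p = 0.134), and that of G6pdx (log2 change -0.16, adjusted p = 0.0233) was lost on leaving out any of 3, furthest without Th17p Methanol Div.1 replicate 7 (-0.13, adjusted p = 0.0842).

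In unsorted Th17n cells DHEA was compared with methanol in the same way. Il17a (chromosome 1, 20730905 to 20734496, plus strand) fell from 364 ± 90.4 to 19.5 ± 15.9 TPM (SD, n = 5 and 5; log2 change -4.48, SE 0.442, adjusted p = 1.82e-13), Il17f from 4997 ± 544 to 923 ± 254 (log2 change -2.47, adjusted p = 3.93e-17), and Il23r (-1.94), Il9 (-1.5) and Il10 (-0.98) fell as well. Cd5l, a regulator of Th17 pathogenicity, fell by 3.44 (adjusted p = 1.49e-16). The chemokine gene Xcl1 rose from 1.01 ± 1.18 to 97.0 ± 36 TPM (log2 change 5.69, adjusted p = 1.23e-10) and Ms4a4b from 4.29 ± 1.27 to 70.2 ± 16.4 (log2 change 3.75, adjusted p = 2.76e-28). The inhibitory receptor gene Lag3 rose from 8.89 ± 1.9 to 50.7 ± 8.98 TPM (log2 change 2.39, adjusted p = 1.42e-23).

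Of genes of naive and quiescent cells, 13 of 15 rose and 0 fell, or 15 and 0 adjusted over the list alone. The median was 0.68 (adjusted p = 2.71e-11, and adjusted p = 0.00828 with an estimated correlation). Ccr7 changed by 1.33 and Tcf7 by 1.28. Ribosome biogenesis genes were lower, as 0 of 20 rose and 20 fell, as many when adjusted over the list alone. Their median was -0.42 (adjusted p = 4.9e-13, and adjusted p = 0.0275 with an estimated correlation). Mybbp1a changed by -0.57 and Ncl by -0.45. Of Treg genes, 9 of 12 rose and 0 fell, as many when adjusted over the list alone. The median was 0.43 (adjusted p = 0.00017, and adjusted p = 0.0249 with an estimated correlation). Lrrc32 changed by 2.31 and Nrp1 by 0.98, although Foxp3 itself did not pass (log2 change 0.29, adjusted p = 0.141). Of TGFb targets, 9 of 12 rose and 0 fell, or 10 and 0 adjusted over the list alone. Their median was 0.42 (adjusted p = 0.000334, and adjusted p = 0.0271 with an estimated correlation). Ldlrad4 changed by 0.80 and Tgfbr1 by 0.58. Of receptor activation genes, 14 of 17 rose and 0 fell, or 14 and 1 adjusted over the list alone. The median was 0.75 (adjusted p = 1.61e-07, and adjusted p = 0.0249 with an estimated correlation). Nr4a3 changed by 1.60. Of inhibitory receptor genes, 5 of 8 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.63 (adjusted p = 0.00238, and adjusted p = 0.028 with an estimated correlation). Tigit changed by 1.28. Of interferon response genes, 7 of 12 rose and 1 fell, as many when adjusted over the list alone. The median was 0.37 (adjusted p = 0.00178, and adjusted p = 0.0275 with an estimated correlation). Polyamine genes were lower, as 1 of 13 rose and 8 fell, or 2 and 8 adjusted over the list alone. Their median was -0.37 (adjusted p = 0.00741, and adjusted p = 0.0823 with an estimated correlation). The spermidine synthase gene Srm changed by -1.84. Of G2 and M phase genes, 0 of 26 rose and 23 fell, as many when adjusted over the list alone. The median was -0.35 (adjusted p = 2.36e-08, and adjusted p = 0.114 with an estimated correlation). Of core Th17 genes, 3 of 16 rose and 8 fell, or 4 and 8 adjusted over the list alone. Their median was -0.29 (adjusted p = 0.00656, and adjusted p = 0.135 with an estimated correlation). Of the non-pathogenic signature, 0 of 7 rose and 5 fell, as many when adjusted over the list alone. The median was -0.54 (adjusted p = 0.0213, and adjusted p = 0.135 with an estimated correlation). Il1rn changed by -2.14. Of the pathogenic one, 6 of 15 rose and 1 fell, as many when adjusted over the list alone. Their median was 0.11 (adjusted p = 0.0305, and adjusted p = 0.148 with an estimated correlation). Glycolysis genes had no common direction, as 5 of 19 rose and 8 fell, as many when adjusted over the list alone. The median was -0.06 (adjusted p = 0.234, and adjusted p = 0.638 with an estimated correlation). Pgam1 changed by -0.35 and Ldha by -0.40. Pentose phosphate genes did not pass as a list, as 1 of 12 rose and 5 fell, as many when adjusted over the list alone. Their median was -0.12 (adjusted p = 0.185, and adjusted p = 0.466 with an estimated correlation). G6pdx changed by -0.23 and Pgd by -0.69. The natural killer cell granule gene Nkg7 (2.78), Ecm1 (2.65) and Akr1c18 (2.65) rose among the furthest, and Cyp1b1 (-2.86), Ildr1 (-2.36) and Gja5 (-2.23) fell among the furthest. B cell markers summed to 14.5 ± 3.92 TPM with DHEA and 4.96 ± 1.07 with methanol. Of 4924 genes changed, 2220 were higher and 2704 lower, or 2603 and 2430 after rescaling. Il22 (adjusted p = 0.15) and Tbx21 (adjusted p = 0.946) did not pass.

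In Th17n Div.1 cells DHEA lowered Il17a from 141 ± 53.9 to 27.1 ± 18 TPM (log2 change -2.49, adjusted p = 5.25e-06) and Il17f from 3592 ± 396 to 1457 ± 431 (log2 change -1.34, adjusted p = 7.47e-08), with Il23r at -1.42 and Cd5l at -1.97. Of genes of naive and quiescent cells, 14 of 15 rose and 0 fell, as many when adjusted over the list alone. The median was 0.49 (adjusted p = 9.87e-09, and adjusted p = 0.0211 with an estimated correlation). Of receptor activation genes, 13 of 17 rose and 0 fell, as many when adjusted over the list alone. Their median was 0.88 (adjusted p = 1.93e-08, and adjusted p = 0.0211 with an estimated correlation). Tnfrsf9 changed by 2.04. Of Treg genes, 8 of 12 rose and 0 fell, as many when adjusted over the list alone. The median was 0.38 (adjusted p = 0.000413, and adjusted p = 0.0295 with an estimated correlation). Of ribosome biogenesis genes, 0 of 20 rose and 18 fell, or 0 and 19 adjusted over the list alone. Their median was -0.27 (adjusted p = 5.09e-12, and adjusted p = 0.0358 with an estimated correlation). Of oxidative phosphorylation genes, 0 of 34 rose and 14 fell, as many when adjusted over the list alone. The median was -0.10 (adjusted p = 0.00011, and adjusted p = 0.0295 with an estimated correlation). Ndufv1 changed by -0.30 and Atp5a1 by -0.21. Of p53 targets, 9 of 16 rose and 0 fell, or 11 and 0 adjusted over the list alone. Their median was 0.50 (adjusted p = 2.35e-05, and adjusted p = 0.0643 with an estimated correlation). Cdkn1a changed by 1.89. Ms4a4b (3.46), Xcl1 (2.68), Lad1 (2.26) and Nkg7 (2.21) rose among the furthest, and Cyp1b1 (-1.84) and the homing receptor gene Gpr15 (-1.72) were among those that fell furthest. Pgam1 (adjusted p = 0.248), G6pdx (adjusted p = 0.133), Foxp3 (adjusted p = 0.579) and Tbx21 (adjusted p = 0.29) did not pass. Of 3910 genes changed, 2355 were higher and 1555 lower, or 2032 and 1972 after rescaling. B cell markers summed to 13.8 ± 2.48 TPM with DHEA and 5.33 ± 0.996 with methanol. The call of Il22 (log2 change -1.13, adjusted p = 0.0249) was lost on leaving out any of 4 libraries in turn, furthest without Th17n Methanol Div.1 replicate 7 (-0.74, adjusted p = 0.174).

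The effect of DHEA in Th17p minus that in Th17n differed for 1578 genes in unsorted cells, 860 of them higher, or 940 of 1744 after rescaling. Ccl3 (log2 change -4.19, adjusted p = 6.74e-06), S100a6 (-3.87), Xcl1 (-3.41), Il22 (log2 change -3.31, adjusted p = 2.13e-05), Tbx21 (log2 change -1.5, adjusted p = 1.54e-05) and Il23r (log2 change -1.31, adjusted p = 0.000196) were negative, and Gzmb (log2 change 3.05, adjusted p = 3.55e-11) positive. Il17a showed no detectable difference (0.82, adjusted p = 0.441). In Div.1 cells 1695 genes differed, 693 of them higher, or 872 of 1729 after rescaling, with Il23r (log2 change -1.39, adjusted p = 9.34e-05), Il17f (log2 change -1.23, adjusted p = 0.000863), Tbx21 (log2 change -1.21, adjusted p = 0.000422) and Nkg7 (-2.27) negative and Gzmb (log2 change 3.09, adjusted p = 1.13e-10) and Sap30 (2.60) positive. At a pseudocount of 0.1 the difference of Il23r was -0.125 in Total (adjusted p = 0.905) and turned to 0.08 in Div.1 cells (adjusted p = 0.921). In Total those of Il22 (adjusted p = 0.0957) and Xcl1 (adjusted p = 0.389) did not pass then. Between the sorts, the effect of DHEA in Div.1 minus that in Total differed in Th17p cells for 1057 genes, 597 of them higher, or 487 of 1166 after rescaling. Il17a (log2 change 2.54, adjusted p = 0.0043), Lum (log2 change 1.87, adjusted p = 2.06e-07) and Pgam1 (log2 change 0.24, adjusted p = 0.0085) were positive and Apol7e (-1.31) negative. In Th17n cells 725 genes differed, 546 of them higher, or 220 of 552 after rescaling (260 in all in a fit on the groups compared alone, 435 with the library of well A4), with Il17f (log2 change 1.13, adjusted p = 0.00786), Pdpn (1.66) and Pgam1 (log2 change 0.28, adjusted p = 0.00328) positive and the interferon-induced gene Gbp2 (log2 change -1.43, adjusted p = 4.72e-05) negative. This count moved with single libraries, from 365 without Th17n Methanol Div.1 replicate 6 to 1059 without Th17n Methanol Div.1 replicate 10. The call of Il17a in that comparison (log2 change 1.99, adjusted p = 0.0389) was lost on leaving out any of 11 libraries in turn, furthest without Th17n DHEA Total replicate 9 (1.72, adjusted p = 0.108).

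To place each response between the 2 cell types, 200 genes higher in Th17p and 200 higher in Th17n were chosen in the libraries of the other solvent, and the log2 changes were averaged over both sets with the sign turned for the Th17n-high genes. By this mean EGCG moved both cell types toward the Th17p side on balance. This mean was 0.19 in Th17p Total (adjusted p = 1.26e-08), 0.26 in Th17p Div.1 (adjusted p = 2.22e-13), 0.31 in Th17n Total (adjusted p = 2.65e-18) and 0.41 in Th17n Div.1 cells (adjusted p = 5.12e-22), with the Th17p-high genes up by 0.71 and the Th17n-high genes at -0.10 in the last. In Th17p cells the Th17n-high genes rose too, by 0.074 in Total and 0.052 in Div.1. On balance DHEA moved the types toward each other, with -0.19 in Th17p Total (adjusted p = 7.35e-13), -0.10 in Th17p Div.1 (adjusted p = 0.000477), 0.23 in Th17n Total (adjusted p = 4.53e-11) and 0.20 in Th17n Div.1 cells (adjusted p = 2.62e-09). Both sets rose in Div.1 cells, the Th17p-high by 0.078 and the Th17n-high by 0.283 in Th17p, and by 0.453 and 0.056 in Th17n. The level of the libraries, as the mean of the Th17p-high minus that of the Th17n-high genes, went from -1.89 ± 0.134 (SD, n = 4) with DMSO to -1.08 ± 0.082 (n = 5) with EGCG in Th17n Div.1 cells, and stood at 2.21 ± 0.071 (n = 4) in Th17p Div.1 cells with DMSO. With the library of well A4 as labelled none of the 8 passed (lowest adjusted p = 0.256), and EGCG in Th17n Div.1 cells gave -0.01.

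**Figure D4:**
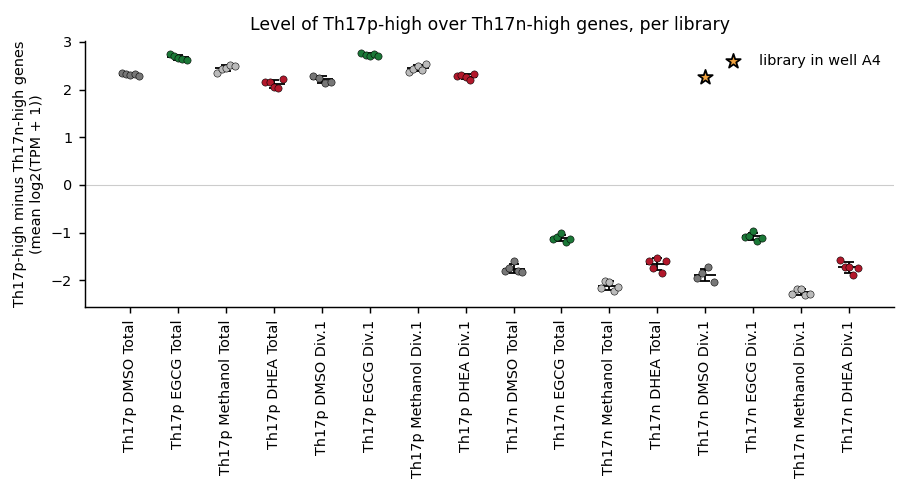
Mean log2(TPM + 1) of the Th17p-high genes minus that of the Th17n-high genes for each library, by group, with the group mean and 1 SD. The star is the library of well A4, at 2.26, where the other libraries with its label reach at most -1.73.

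Cells that had divided once were compared with the unsorted cells of the same type, over both solvents, to show what the sort itself changed. In Th17p cells the changes were small: 2068 genes differed, 921 higher and 1147 lower in Div.1 (1182 and 1131 after rescaling), and 3 and 10 of them at least 2-fold. Il9 (log2 change -1.53, adjusted p = 1.89e-05), Mt2 (log2 change -1.24, adjusted p = 3.92e-08), Lum (-1.11) and Cth (-0.88) were lower, and Apol7e (log2 change 0.85, adjusted p = 1.04e-07) and Gbp2 (0.52) higher. Of G2 and M phase genes, 11 of 26 were higher and 1 lower, or 12 and 1 adjusted over the list alone. The median was 0.11 (adjusted p = 1.03e-05, and adjusted p = 0.439 with an estimated correlation). Ube2c differed by 0.34 and Aurkb by 0.27. Of interferon response genes, 6 of 12 were higher and 1 lower, or 8 and 2 adjusted over the list alone. Their median was 0.27 (adjusted p = 0.00139, and adjusted p = 0.0695 with an estimated correlation). Of cholesterol synthesis genes, 1 of 23 were higher and 9 lower, or 1 and 12 adjusted over the list alone. The median was -0.13 (adjusted p = 0.000639, and adjusted p = 0.439 with an estimated correlation). Il17a (adjusted p = 0.0609), Il17f (adjusted p = 0.12), Il22 (adjusted p = 0.273), Il23r (adjusted p = 0.53), Pgam1 (adjusted p = 0.178) and G6pdx (adjusted p = 0.0836) did not pass.

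In Th17n cells 2337 genes differed between Div.1 and unsorted cells, 619 higher and 1718 lower in Div.1, or 1074 and 1188 after rescaling. Il17a was lower in Div.1, at 120.1 ± 43.2 TPM with DMSO (n = 4) and 141 ± 53.9 with methanol (n = 5) against 367 ± 121 and 364 ± 90.4 in Total (log2 change -1.51, adjusted p = 0.000265). Il17f (log2 change -0.65, adjusted p = 0.000427), Il23r (-0.51), Il10 (-0.52), Ccl20 (-1.18), Pdpn (-1.15) and Cd5l (-1.25) were lower as well. Foxp3 (log2 change 0.53, adjusted p = 0.000453), Xcl1 (1.80) and Lsp1 (0.94) were higher. With the library of well A4 as labelled the change of Foxp3 turned to -0.09 (adjusted p = 0.9). Of cholesterol synthesis genes, 0 of 23 were higher and 17 lower, or 0 and 18 adjusted over the list alone. Their median was -0.23 (adjusted p = 8.65e-08, and adjusted p = 0.238 with an estimated correlation). Idi1 differed by -0.62. Of glycolysis genes, 0 of 19 were higher and 11 lower, or 1 and 11 adjusted over the list alone. The median was -0.16 (adjusted p = 0.000352, and adjusted p = 0.422 with an estimated correlation). Hk2 differed by -0.34 and Pgam1 by -0.20. G6pdx was at -0.14.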

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

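The tests of the p53 targets and of Il17f and Ccl20 were chosen after the results were seen, while those of the library of well A4 and of other splits of the libraries were planned.

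The library of well A4 carried the label Th17n DMSO Div.1, and its level of Th17p-high over Th17n-high genes was 2.261. The other libraries with that label lay between -2.036 and -1.727, and the Th17p DMSO Div.1 libraries between 2.142 and 2.294. It held 388 TPM of Il22 and 0.394 TPM of Foxp3, and across genes, which are not independent replicates, its correlation was 0.994 with the mean of Th17p DMSO Div.1 and 0.965 with that of Th17n DMSO Div.1. These values argue against its label, with a mislabelled Th17p library as a candidate.

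The p53 targets rose with EGCG in both cell types and the G2 and M phase genes fell. In Th17n cells that fall did not pass with an estimated correlation (adjusted p = 0.177 in Total and 0.256 in Div.1). Had EGCG cells only divided fewer times, Div.1 cells would have shown less of it. Yet the p53 median was 1.61 in Th17p Div.1 and 1.36 in Total. TPM scaling was argued against too, as the lowest EGCG median after rescaling was 0.693. An oxidative stress response stays open, undecided by 16 NRF2 targets, of which 1 rose and 6 fell in Th17p Total. Both lists moved the same way with DHEA, at medians of 0.39 to 0.60 and -0.35 to -0.23. For DHEA only p53 in Th17p Div.1 passed with an estimated correlation. A p53 response to either compound is an untested hypothesis.

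The change with EGCG was higher in Th17n Div.1 than in Total cells, by 1.04 for Il17f and 1.88 for Ccl20. DMSO Div.1 controls that were out of place could produce this, since DMSO controls changed by -0.81 and -1.39 from Total to Div.1 (adjusted p = 0.00335 and 0.00377). The methanol controls moved the same way, by -0.476 (adjusted p = 0.176) and -0.97 (adjusted p = 0.0978), without passing, so the 2 possibilities cannot be told apart. The scaling of TPM was argued against, as rescaling left 0.956 and 1.798. A response to EGCG that depends on division stays open as a biological explanation, untested beyond this comparison.

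The responses to EGCG differed between the cell types for 2127 genes in Total and 1867 in Div.1 cells, and between the sorts for 274 genes in Th17p (160 with the library of well A4, 467 without columns 1 and 10, 479 in a fit on the groups compared alone) and 1420 in Th17n cells. For DHEA the numbers were 1578, 1695, 1057 and 725 (435 with that library, 260 in such a fit). With EGCG, Il22 moved in opposite directions in the 2 cell types in Total cells (difference -3.586). In Div.1 cells Il17a (-3.112), Il17f (-3.461), Il22 (-3.919) and Pgam1 (-0.449) did so, though after rescaling Pgam1 in Th17n cells stood at 0.024 (adjusted p = 0.645).

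Of 197 tests for a single library far from the rest of its group 16 found one, where chance gives about 1 in 20, or 9.9. One gene of the fixed list was left out of these tests after they had been run. In the TPM sum Th17n EGCG Total replicate 1 stood at 880100, in the genes of at least 1 TPM Th17n DMSO Total replicate 4 at 9454, and in the share of the 10 most abundant genes Th17p DMSO Div.1 replicate 3 at 7.242%. In TPM, Il17a stood at 444.7 in Th17n EGCG Div.1 replicate 1 and at 23.96 in Th17p DHEA Total replicate 8. Il22 stood at 7.359 in Th17n DMSO Div.1 replicate 3, at 8.827 in Th17n Methanol Div.1 replicate 7 and at 380.1 in Th17p DMSO Div.1 replicate 2. Il23r stood at 3.77 in Th17p EGCG Total replicate 2, and Tbx21 at 3.991 in Th17n EGCG Div.1 replicate 1 and at 61.92 in Th17p Methanol Total replicate 10. Il9 stood at 1626 in Th17n EGCG Total replicate 4 and at 5.872 in Th17p EGCG Total replicate 1. Pgam1 stood at 830 in Th17n DHEA Total replicate 9. G6pdx stood at 65.52 in Th17n Methanol Total replicate 10 and at 51.78 in Th17p EGCG Div.1 replicate 3.

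Chance was unlikely for all 20 counts of genes called, as only the real split of 100 gave as many. Compared groups lay in different well rows, an effect not tested. For EGCG the real counts and the highest of the other splits were 4794 and 2837 in Th17p Total, 4869 and 3747 in Th17p Div.1, 3760 and 1915 in Th17n Total, and 3720 and 2623 in Th17n Div.1 cells. For DHEA they were 5095 and 3213, 3982 and 1928, 4924 and 2725, and 3910 and 2459 in the same order. Between the cell types they were 6127 and 4161 in Total and 6465 and 4345 in Div.1, and between the sorts 2068 and 543 in Th17p and 2337 and 1905 in Th17n. For the differences in response, split after removing the additive effects, they were for EGCG 2127 and 949 (cell types, Total), 1867 and 447 (cell types, Div.1), 274 and 54 (sorts, Th17p) and 1420 and 87 (sorts, Th17n). For DHEA those were 1578 and 510, 1695 and 200, 1057 and 8, and 725 and 274.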

How the results depend on the processing

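Every alternative was planned except that without the wells of columns 1 and 10, which was chosen after seeing the data. Where a count or call changed, the cause was not tested unless given. Most counts of genes called stayed within 1.5 times their value under every alternative, and the exceptions were differences between sorts in the response to a compound. For EGCG in Th17p cells (274) the count was 669 with the well column as a block, 479 in a fit on the groups compared alone, 160 with the library of well A4 in its labelled group and 467 without columns 1 and 10. For DHEA in Th17p cells (1057) it was 1587 with the block. For DHEA in Th17n cells (725) it was 1280 with the block, 260 in a fit on the groups compared alone and 435 with the library of well A4. Leaving out 1 library at a time moved it from 365 (without Th17n Methanol Div.1 replicate 6) to 1059 (without Th17n Methanol Div.1 replicate 10), and 5 of 20 such counts lay outside 1.5 times. With the library of well A4 in its labelled group, the shift toward the Th17p side did not pass in any of the 8 cases. With EGCG it was 0.185 in Th17p Total, 0.258 in Th17p Div.1 and 0.306 in Th17n Total cells (adjusted p = 0.256 each), and turned to -0.01 in Th17n Div.1 cells (adjusted p = 0.83). With DHEA it was -0.192 in Th17p Total, 0.233 in Th17n Total and 0.204 in Th17n Div.1 cells (adjusted p = 0.256 each) and -0.116 in Th17p Div.1 cells (adjusted p = 0.623). By construction the model has 1 spread per gene over all groups, which that library widened. Of 189 list calls 46 passed with an estimated correlation, and no list reversed under any alternative run. Of the named genes 3 reversed: Il23r at a pseudocount of 0.1 (DHEA, cell types, Div.1; 0.084, adjusted p = 0.921), and with the library of well A4 Foxp3 between the sorts in Th17n cells (-0.086, adjusted p = 0.9) and in their response to EGCG (0.434, adjusted p = 0.732). Other named results that were called in either fit kept their direction, and those that crossed the threshold numbered 82 weaker and 7 stronger with that library, 30 and 12 in a fit on the groups compared alone, 28 and 2 at a pseudocount of 0.1, 25 and 0 without the filter, 15 and 4 without columns 1 and 10, 6 and 9 after rescaling, 0 and 5 with the block, and 289 and 40 over all fits without 1 library. Libraries of 2 groups with the same number (well column) deviated from their group means with correlations from -0.002 to 0.315, and 25 of 74 such pairs were over 0.1, the limit for pairing. In 0 of 16 pairs of groups were all of them over it, so the main fit had no block, although in 57 of 74 the number was the best match both ways. Over pairs of groups the median mean correlation was 0.102 for the same number and -0.026 for different ones. By the data, not the design, same-numbered libraries shared variation, which the main p-values ignore. TPM carry no depth, so no limit from depth could be computed.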

Other observations

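The list tests were planned, while the counts of genes shared between comparisons and the component within groups were computed after the results were seen.

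Some gene groups moved in comparisons not yet described for them. Targets of ATF4 were lower with EGCG in Th17n Total cells too, as 2 of 25 rose and 12 fell, or 4 and 12 adjusted over the list alone. Their median was -0.21 (adjusted p = 0.00145, and adjusted p = 0.415 with an estimated correlation). Heat shock genes were lower there as well, as 0 of 10 rose and 6 fell, as many when adjusted over the list alone. The median was -0.17 (adjusted p = 0.00101, and adjusted p = 0.136 with an estimated correlation). With EGCG in Th17p Total cells, among LXR targets, 2 of 8 rose and 5 fell, as many when adjusted over the list alone. Their median was -0.33 (adjusted p = 0.00647, and adjusted p = 0.097 with an estimated correlation). With DHEA in Th17p Total cells, among interferon response genes, 7 of 12 rose and 1 fell, as many when adjusted over the list alone. The median was 0.34 (adjusted p = 0.0168, and adjusted p = 0.116 with an estimated correlation). With DHEA in Th17p Div.1 cells, among citric acid cycle genes, 0 of 21 rose and 15 fell, as many when adjusted over the list alone. Their median was -0.19 (adjusted p = 3.46e-08, and adjusted p = 0.0593 with an estimated correlation). Targets of AhR were lower in Th17p than in Th17n Total cells, as 1 of 6 were higher and 4 lower, as many when adjusted over the list alone. The median was -1.12 (adjusted p = 0.00832, and adjusted p = 0.146 with an estimated correlation).

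The genes called for EGCG and for DHEA overlapped. In Th17p Total cells 2854 were called for both, of which 1195 were higher and 1010 lower with both and 649 went in opposite directions, where independence would give 1192 opposite. In Th17n Total cells 2312 were called for both and 326 were opposite. The solvents differed between the compounds, and the correlation of changes across genes was 0.459 and 0.499, where genes are not independent replicates. Between Total and Div.1 cells, 3454 genes were called for EGCG in both sorts of Th17p and 34 were opposite, against 1927 and 159 in Th17n cells.

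Markers of myeloid cells summed to between 0.036 and 2.05 TPM per library. Those of red cells summed to 7.11 ± 12.8 TPM (SD, n = 5) in Th17n EGCG Total, where the highest library reached 30.01 TPM, and to 0.755 ± 0.411 in Th17n DMSO Total. Among the B cell markers, H2-Ab1 (up to 23.3 TPM) and Cd74 (up to 10.97 TPM) made up most of the sum, while Ms4a1 reached 0.208 TPM at most. Among the CD8 T and NK cell markers, Cd8b1 reached 26.9 and Klrd1 24.2 TPM, and Cd8a 0.557 TPM.

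Within groups, the first component of the residuals held 7.52% of the variance. In 16 of 16 groups the library of well column 1 or column 10 lay outermost on it, with a mean of -12.6 for column 1 and 7.8 for column 10.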
